A study of Mus musculus with 6 samples.

How the data were processed

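Total RNA of liver from untreated 6-week-old male mice was measured on 6 one-colour (Cy3) Agilent oligonucleotide arrays, 3 WT and 3 Sec15 KO, 1 array per sample. The deposited values are intensity per spot, read out with Agilent Feature Extraction and not normalised between arrays, per the file headers: the processed signal is the spot's brightness after background subtraction and detrending, with low values replaced by a small positive surrogate. The deposited files also hold other flags, coded 0 or 1 per spot, for signal well above background, saturation and outliers. Groups and replicate numbers were taken from the labels. Arrays with the same scan date in their headers were taken to share a slide, so a slide here is a group of arrays by scan date.

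Each array held 43020 non-control spots for 39429 probes. Between 178 and 236 outlier spots per array were left out, no spot was saturated, and spots of 1 probe were averaged. The log2 processed signal minus the array's 75th percentile over non-control probes was used. A probe was kept when it was well above background on at least 3 of the 6 arrays, which left 27024 probes. The files give no gene names, so each probe's transcript accession was matched to a RefSeq gene table of assembly GRCm38.p6, for names alone. Of the probes, 27234 matched 1 symbol and 12195 matched none. For each gene the probe with the highest mean over all arrays was used, which gave 22810 genes, 15544 of them with a symbol. The number of arrays limits the precision.

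WT and Sec15 KO were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the packages jsonlite 2.0.0 and data.table (version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. Genes with an unadjusted p under 0.05 and at least a 2-fold change were counted as well. The Sec15 probes were also compared by an exact two-sided permutation test. Of 59 gene lists, the 58 with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. The lists, comparisons, tests between the groups, rule for naming genes and all alternatives except cyclic loess and the arrays of slide 1 alone were chosen before the data were examined. Most tests of explanations were chosen later.

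The genes named were every probe of Exoc6 and Exoc6b, and the 10 largest rises and 10 largest falls with a symbol among genes past the adjusted threshold. These had all 3 KO values on one side of the WT values and were well above background on at least 2 arrays of each group. Up to 5 genes per direction were named that were well above background on all arrays of one group and none of the other, and for each list up to 4 members with the smallest p. Some members that this rule names are not reported here. For genes not well above background in a group, the fold is a lower bound. On simulated data with 22810 genes, limma recovered 42 of 100 genes changed 2-fold and 82 of 100 changed 4-fold, with 3 false calls. Genes were drawn independently there, with no slide effect and no other changed genes. The real comparison called 6747 genes, so neither the recovery nor the false calls carry over to it.

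The alternatives were quantile normalisation, median centring, normexp background correction (offset 50) with quantile normalisation, a filter on all 6 arrays and none, eBayes with trend and robust, array weights, the mean of a gene's probes, the replicate number as a block, the slide as a block, WT replicates 1 and 2 averaged, and each replicate left out. The files hold no mean spot signal, so normexp used the median signal of the spot and of its local background.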

Results

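Liver RNA was compared between mice labelled as Sec15 knockout (KO) and wild-type (WT) mice. Sec15 is a subunit of the exocyst, the complex that tethers secretory vesicles to the plasma membrane, and the series concerns the movement of the transcription factor STAT3 and the fate of blood stem cells. Total RNA from the liver of untreated 6-week-old male mice was labelled with Cy3 and hybridised to 6 one-colour oligonucleotide arrays, with 3 WT and 3 Sec15 KO samples. The labels number the samples as replicates but do not say that each came from its own animal, so the p-values measure the spread between these samples, which may be partly technical. The deposited names of WT replicates 1 and 2 share a number, so these may come from 1 animal, and with both averaged 3725 genes were higher and 2386 lower in KO. Between 64.8% and 70.3% of the 39429 probes gave a signal well above background on an array, and no spot was saturated. By scan date, the 3 WT arrays and KO replicate 2 were taken to share slide 1, and KO replicates 1 and 3 slide 2. An effect of the slide and one of the scan date cannot be told apart. With 6 arrays, their number limits the precision.

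The Sec15 genes were examined first. Mouse Sec15 is encoded by Exoc6 and Exoc6b, and the labels do not say which of them was knocked out or which part was deleted. The single Exoc6 probe, A_52_P219661, was well above background on 1 WT array and on no KO array. Its signal was -3.90 ± 0.11 in WT and -3.80 ± 0.21 in KO on the log2 scale relative to the array's 75th percentile (mean ± SD, n = 3 each), so no fold change is given. Exoc6b probe A_52_P265544 was well above background on none of the arrays. The other Exoc6b probe, A_55_P1997415, was well above background on all 6 arrays and read 0.54 ± 0.23 in WT and 0.02 ± 0.11 in KO (mean ± SD, n = 3 each). Its signal fell by 0.53 on the log2 scale (SE 0.15, 1.44-fold lower, limma adjusted p = 0.0426), with the 3 KO values below the 3 WT values. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. With the slide as a block the difference was -0.58 with an adjusted p of 0.128. The probe kept its direction in all 19 alternative settings and lost its call in 10 of them. A probe outside the deleted part checks nothing, so these probes neither bear out nor contradict the genotype labels. None of the 7 measured subunits of the exocyst other than Sec15 passed the test, and their median log2 fold change was 0.11, -0.02 after cyclic loess normalisation and 0.31 with the slide as a block (adjusted p = 0.445).

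**Figure D1:**
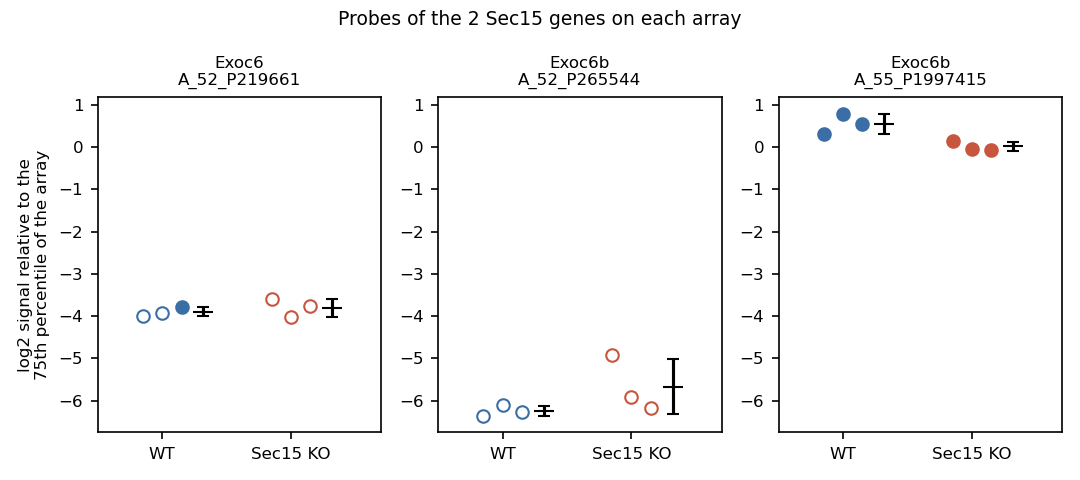
Signal of the 3 probes of Exoc6 and Exoc6b on each array (log2, relative to the array's 75th percentile), in WT (blue) and Sec15 KO (red) liver. Filled points were well above background and open points were not; bars give the mean ± SD of 3 arrays. Only the Exoc6b probe A_55_P1997415 was measured on all 6 arrays, at 0.54 in WT and 0.02 in KO.

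The main comparison asked which liver genes differ between Sec15 KO and WT. The 10 largest rises among named genes in KO liver come first. Mt2, a metal-binding metallothionein, rose 27.8-fold (log2 fold change 4.80, SE 0.76, adjusted p = 0.0117), and Mt1 rose 12.5-fold (log2 fold change 3.64, SE 0.65). Cyp4a14, a fatty acid hydroxylase and target of the nuclear receptor PPARa, rose 15.4-fold (log2 fold change 3.95, SE 0.21, adjusted p = 0.00219). Cyp2b10, a drug-metabolising P450, rose 13.8-fold (log2 fold change 3.79, SE 0.26). Vldlr, the very low density lipoprotein receptor, rose 12.6-fold (log2 fold change 3.66, SE 0.29). Prelid2 rose 12.0-fold (SE 0.18 on the log2 scale) and Ankrd37 8.08-fold (SE 0.10). The adult beta globin genes Hbb-bs and Hbb-b2 rose 9.93-fold (SE 0.28) and 7.67-fold (SE 0.16), although the probes of such near-identical copies may share signal. Lpin1, a phosphatidic acid phosphatase, rose 7.56-fold (log2 fold change 2.92, SE 0.21). On slide 1 alone, KO replicate 2 lay above the WT mean by between 2.63 (Lpin1) and 5.49 (Mt2) on the log2 scale for these 10 genes. The rule for naming them fixed this direction, so only the sizes are informative. With the slide as a block, 9 of them passed the test and Mt1 did not (adjusted p = 0.0536). Without WT replicate 3, Mt2 (adjusted p = 0.0578) and Mt1 (adjusted p = 0.0647) lost their calls, as they did without KO replicate 3 (adjusted p = 0.0555 and 0.0644).

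The 10 largest falls among named genes follow. Fnd3c2 was 14.7-fold lower in KO liver (log2 fold change -3.87, SE 0.24, adjusted p = 0.00271), and the G protein-coupled receptor gene Gpr75 was 14.1-fold lower (SE 0.42). Nhlrc1, a ubiquitin ligase gene, was 14.1-fold lower (SE 0.39) on its brightest probe, while its second probe read 0.61 higher on the log2 scale. Samt1c, Try5 (a trypsin, also on the list of pancreas markers), Zfp219, Clec2g, Zfp536, Speg (a kinase of striated muscle) and Uprt were between 11.3-fold (Uprt) and 13.5-fold (Samt1c) lower. The second probe of Speg differed by -0.05, and the other 8 genes had no second probe that passed the filter. KO replicate 2, on the slide of the WT arrays, differed from the WT mean by between -1.81 (Speg) and -4.56 (Nhlrc1) on the log2 scale. Here too the naming rule fixed the direction. The calls of Try5, Clec2g, Speg and Uprt ended with the slide as a block (adjusted p between 0.0572 and 0.114), and also without WT replicate 3 or KO replicate 3 (adjusted p between 0.0535 and 0.086). Samt1c and Zfp536 lost their calls without WT replicate 2 or 3 or KO replicate 1 or 3 (adjusted p between 0.052 and 0.0786). A further 5 named genes were well above background on all KO arrays and no WT array: Rhd, the RhD blood group antigen of red cells (at least 5.21-fold higher in KO, adjusted p = 0.00292), Dppa2 (at least 4.92-fold), Slc22a27 (at least 4.49-fold), Trim59 (at least 4.45-fold, with 3.72 on the log2 scale on its second probe) and the beta defensin Defb1 (at least 4.31-fold). In the other direction stood the olfactory receptor genes Olfr1511 (at least 6.68-fold lower in KO), Olfr1016 (at least 5.07-fold) and Olfr733 (at least 4.88-fold), with Dnah11, a dynein heavy chain (at least 6.32-fold), and Fzd3, a Wnt receptor (at least 5.84-fold). Of these 10 genes, Defb1, Olfr1511, Dnah11, Olfr1016 and Olfr733 lost their call with the slide as a block. Without WT replicate 3 the same 5 and Fzd3 lost it (adjusted p between 0.0544 and 0.0694). In all, 55 genes, with or without a symbol, were well above background on all KO arrays and no WT array. For all WT arrays and no KO array the number was 441. Each KO array had fewer probes well above background (64.8% to 65.45%) than each WT array (67.3% to 70.3%). The 2 counts therefore do not start from equal detection.

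**Figure D2:**
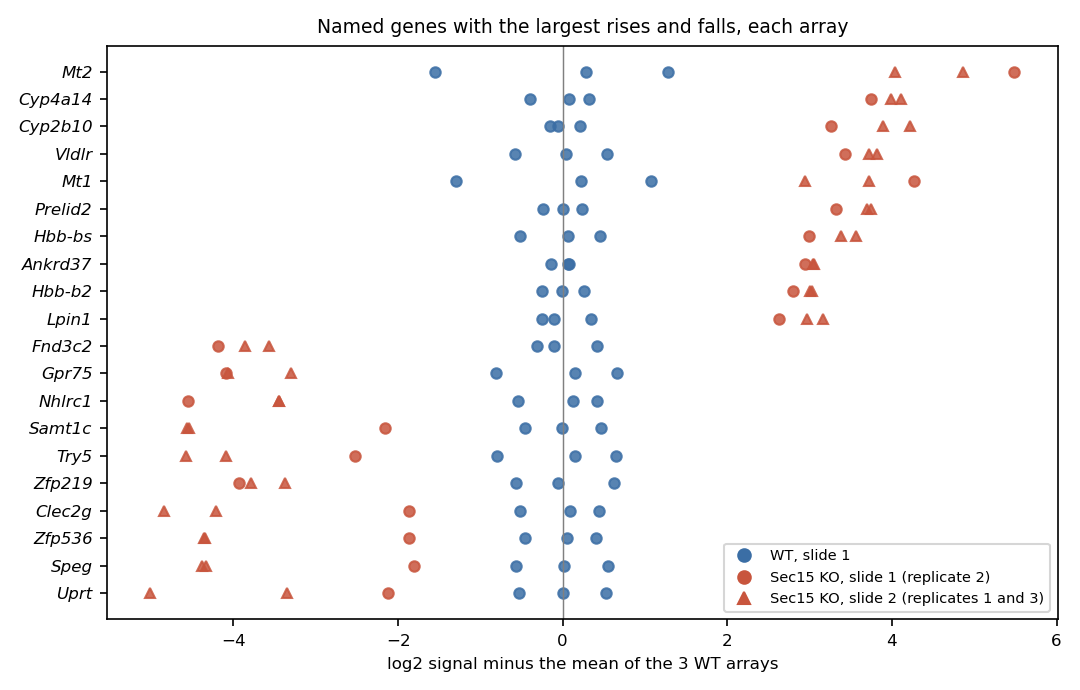
Signal of the 20 named genes with the largest rises and falls on each array (log2, minus the mean of the 3 WT arrays); circles are arrays of slide 1 and triangles arrays of slide 2, WT in blue and Sec15 KO in red. KO replicate 2, the red circle, lies on the same side as the other KO arrays for all 20 genes, which the rule for naming them required.

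Across 22810 genes tested, 3959 were higher and 2788 lower in Sec15 KO liver at a limma adjusted p under 0.05. Of these, 2946 and 1680 had a gene symbol. At an unadjusted p under 0.05, 10389 genes differed, where chance would give about 1140. The 3 KO values lay on one side of the 3 WT values in 50.8% of genes, against 10% by chance. Among genes with an unadjusted p under 0.05 and at least a 2-fold change, 597 were higher and 1685 lower, so 73.8% of these larger changes were falls. Sensory receptor genes (olfactory, vomeronasal and taste receptors) made up 128 of the 2-fold falls and 8 of the 2-fold rises: 21.8% of the 587 measured fell by 2-fold, against 9.00% of other genes of the same brightness. Their median log2 fold change was -0.53, and KO replicate 2 lay at -0.11. The filter admits genes well above background on the WT arrays alone. Without a filter the median over 1359 sensory receptor genes was -0.125, and with normexp and quantile normalisation it was -0.19 over the 587. With a filter on all 6 arrays it was -0.44 over 379, of which 112 were lower at the adjusted threshold, and after cyclic loess it was -0.485 over the 587. The change followed brightness, with a median log2 fold change of -0.29 in the dimmest decile of genes and 0.29 in the brightest. The median of all genes was 0.06, and 0.18 with each array centred on its median, which moved the calls from 58.7% to 69.4% higher (5120 higher and 2253 lower). After cyclic loess the balance turned, with 2472 genes higher and 2852 lower (46.4% higher). Changes below are relative to the 75th percentile, so this shift of the median stands beneath each. A block for the slide left 1158 genes higher and 1067 lower, of which 992 and 874 were also called without it. On slide 1 alone, with KO replicate 2 as the lone KO array assumed to vary like the WT arrays, limma called 0 genes at the adjusted threshold and 6760 at an unadjusted p under 0.05. The calls also leaned on single arrays, with 341 higher and 276 lower without WT replicate 3, 476 and 519 without KO replicate 3, 1484 and 1194 without KO replicate 1, 1186 and 1073 without WT replicate 2, and 5728 and 5069 without KO replicate 2.

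Gene lists chosen before the data were examined were tested next. Of 58 lists, 20 were higher and 5 lower in KO liver than other genes at a camera adjusted p under 0.05 with a preset inter-gene correlation of 0.01. None passed with an estimated correlation, where the lowest adjusted p was 0.492, and 4 lists had an unadjusted p under 0.05 there. For pancreas markers the estimated correlation was -0.051, below the preset one. Their unadjusted camera p still went from 2.62e-05 to 0.0104. Calls lost in that setting, here and below, therefore do not come from correlation between members alone. Values with the slide as a block equal those within slide 1, since slide 2 held KO arrays only. With that block 10 of the 25 lists kept their call, after cyclic loess normalisation, which removes differences that follow brightness, 16 did, and 8 did in both. The KO arm of the blocked comparison is KO replicate 2 alone, assumed to vary like the other arrays, so a call kept or lost there rests on 1 KO array. The order of the lists below does not rank them. The members named in each list are among the 4 with the smallest p, and any others were chosen after their values were seen. No list's median changed when genes not well above background in a group were set to their bound.

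Genes of red blood cells changed in both directions. Of 31 measured erythroid markers, 14 rose and 5 fell (16 and 5 adjusted over the list alone), with a median log2 fold change of 0.48 (adjusted p = 0.00277; adjusted p = 0.492 with an estimated correlation). Kel, the Kell blood group protein, was not well above background in WT and at least 2.51-fold higher in KO. Bpgm, which makes the haemoglobin ligand 2,3-bisphosphoglycerate, rose 3.54-fold (SE 0.09 on the log2 scale) and the beta globin Hbb-b2 7.67-fold. The alpha globin Hba-a1 rose 4.04-fold and the anion exchanger Slc4a1 4.22-fold. The embryonic globin Hbb-y fell by 1.65 on the log2 scale, and Ube2l6, Tspo2, Rhag and Xk were also lower. Alas2, the first enzyme of haem synthesis in red cells, stood at 0.02 (SE 0.21). The list's median within slide 1 was 0.46 (adjusted p = 0.0175 with the slide as a block). In 29 measured genes of iron handling, 10 rose and none fell (12 and 1 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00321; adjusted p = 0.492 with an estimated correlation). These included Tfrc, the transferrin receptor, at 2.87-fold (SE 0.09; second probe 0.32), the iron exporter Slc40a1 at 2.04-fold (SE 0.10), Ncoa4 at 1.97-fold and Slc39a14 at 1.67-fold. This list's call ended after cyclic loess (adjusted p = 0.0835, median 0.25), and within slide 1 the median was 0.25. No member of the heme synthesis list other than Flvcr1 passed the test (15 measured, median 0.02).

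Liver genes that differ between the sexes were tested as a male-biased and a female-biased list. Of 24 measured male-biased genes, 10 fell and none rose (11 lower and 1 higher adjusted over the list alone), with a median of -0.32 (adjusted p = 0.000713; adjusted p = 0.668 with an estimated correlation). Cyp4a12a fell by 1.59 (SE 0.10) and Cyp4a12b fell by 1.67 (SE 0.11) on the log2 scale, a pair of close copies whose probes may share signal. Hsd3b5, a steroid dehydrogenase, fell by 1.21 (SE 0.15) and Susd4 fell by 1.03 (SE 0.14). The median within slide 1 was -0.28 (adjusted p = 0.000687 with the slide as a block), and after cyclic loess it was -0.57. Of 19 measured female-biased genes, 11 rose and none fell (12 and none adjusted over the list alone), with a median of 1.1 (adjusted p = 0.00143; adjusted p = 0.668 with an estimated correlation). Cux2, a female-specific repressor in liver, was not well above background in WT and at least 4.20-fold higher in KO. Cyp2b10 rose 13.8-fold, Cyp39a1 4.16-fold (SE 0.20) and Tox 3.90-fold (SE 0.21). Within slide 1 the median was 0.58 and the call ended with the slide as a block (adjusted p = 0.109). The Y-linked genes Ddx3y and Eif2s3y were well above background on all 6 arrays, Kdm5d was on no WT array and 1 KO array, and Uty was on none. Ddx3y was higher in KO by 0.69 (SE 0.16) and Eif2s3y by 0.43 (SE 0.12) on the log2 scale. Xist was well above background on 3 WT arrays and 1 KO array, so its difference of -0.32 (SE 0.34) is against a group mostly not above background.

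Lists of fuel use covered fatty acid oxidation, fasting and respiration. Of 41 measured genes of fatty acid oxidation and PPARa targets, 22 rose and 1 fell, the fall being Hadha (23 and 1 adjusted over the list alone). Their median was 0.54 (adjusted p = 4.25e-05; adjusted p = 0.668 with an estimated correlation) and 0.44 within slide 1 (adjusted p = 0.00718 with the slide as a block). Besides Cyp4a14, the lipid droplet protein gene Plin5 rose 2.52-fold (SE 0.16), Etfdh 1.99-fold (SE 0.12) and Decr1 1.73-fold (SE 0.09), although the second Decr1 probe read -0.01. After cyclic loess the list's median was 0.31. Of 27 measured genes of gluconeogenesis and fasting, 14 rose and none fell (16 and none adjusted over the list alone), with a median of 0.52 (adjusted p = 0.00111; adjusted p = 0.668 with an estimated correlation) and 0.29 within slide 1 (adjusted p = 0.0175 with the slide as a block). After cyclic loess it was 0.24. Ppargc1a, a coactivator induced by fasting, rose 2.90-fold (SE 0.15), the glucose-6-phosphate transporter gene Slc37a4 2.34-fold (SE 0.12) and Ppp1r3b 1.88-fold, beside Lpin1. Of 73 genes of oxidative phosphorylation, 39 rose and none fell (50 and none adjusted over the list alone), with a median of 0.42 (adjusted p = 3.75e-10; adjusted p = 0.668 with an estimated correlation). Atp5a1 rose 2.11-fold (SE 0.13), and Ndufa12, Ndufs1 and Cox7c rose by between 0.59 and 0.70 on the log2 scale. After cyclic loess this list's median was 0.14 (adjusted p = 0.00566), and it was 0.27 within slide 1 (adjusted p = 3.6e-06 with the slide as a block).

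Hormone and daily rhythm were covered by glucocorticoid targets and clock genes. Of 21 measured glucocorticoid targets, 14 rose and 1, Lcn2, fell (17 and 1 adjusted over the list alone), with a median of 1.01 (adjusted p = 3.76e-05; adjusted p = 0.492 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 2.85-fold (SE 0.09), Cdkn1a 4.00-fold (SE 0.15; its second probe read 0.13) and Ddit4 6.61-fold (SE 0.21), beside Lpin1. Within slide 1 the median was 0.62 (adjusted p = 0.00138 with the slide as a block). Of these 21 genes, 15 stand on another list too, among them Mt1 and Mt2. Of 21 measured circadian clock genes, 7 rose and none fell (8 and none adjusted over the list alone), with a median of 0.42 (adjusted p = 0.00277; adjusted p = 0.492 with an estimated correlation). Ciart, a repressor of the clock, was at least 3.03-fold higher in KO, Per1 rose 2.08-fold (SE 0.12), Por 1.70-fold and Avpr1a 1.68-fold. The median within slide 1 was 0.50 (adjusted p = 0.00138 with the slide as a block), and after cyclic loess it was 0.22.

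Pancreas markers, listed because that tissue can be taken along with liver, were tested as a list. Of 18 measured, 10 fell and 1, Amy2a5, rose (12 and 1 adjusted over the list alone), with a median of -0.63 (adjusted p = 0.000253; adjusted p = 0.492 with an estimated correlation). The trypsin Try4 was well above background on 3 WT arrays and 1 KO array, so its difference of -3.80 (SE 0.56) on the log2 scale is against a group mostly not above background. Its relative Try5, well above background on all 6 arrays, fell by 3.73 (SE 0.62) and the insulin gene Ins1 fell by 0.66 (SE 0.11). Within slide 1 the median was -0.61 (adjusted p = 0.000687 with the slide as a block).

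The acute phase and STAT3 target lists did not pass the camera test against other genes. With fry, which does not compare a list with other genes, both did (adjusted p = 0.0388 and 0.0316). Of 36 measured acute phase proteins, liver products that STAT3 drives in inflammation, 10 rose and 4 fell, the same counts as adjusted over the list alone. Their median was 0.29 (adjusted p = 0.0909; adjusted p = 0.686 with an estimated correlation). Fgl1 rose 2.08-fold (SE 0.12), the fibrinogen chain gene Fgb 1.60-fold (SE 0.09) and Itih3 1.53-fold, beside Mt2. Lcn2, Fga, Cd14 and A2m (well above background on 1 KO array) fell, although the second Fga probe read 0.88. Without KO replicate 2 this list passed the test (median 0.31, adjusted p = 0.0498), as it did with the mean of the probes of a gene (median 0.30, adjusted p = 0.0356). Within slide 1 the median was 0.13 (adjusted p = 0.65 with the slide as a block), and after cyclic loess it was 0.02. Of 27 measured STAT3 target genes, 9 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.224; adjusted p = 0.686 with an estimated correlation). Cebpd rose 2.73-fold (SE 0.13) and Cebpb 1.61-fold (SE 0.09), whereas Socs3, a feedback inhibitor of STAT3 signalling, fell by 1.21 (SE 0.14) on the log2 scale. Muc1 and Il4ra were also lower, although the second Il4ra probe read 1.21, and Jak3, not well above background in KO, was at least 1.88-fold lower. The median within slide 1 was 0.40 (adjusted p = 0.2 with the slide as a block), and after cyclic loess it was 0.14. Of 28 measured components of the JAK-STAT3 pathway, 4 rose and 3 fell, with a median of 0.02, a mean of -0.09 and an adjusted p of 0.925. Il6ra, a chain of the interleukin-6 receptor, rose 2.10-fold (SE 0.17), and Ptpn11 rose by 0.50 on the log2 scale. Pias3, an inhibitor of STAT3, was not well above background in KO and at least 3.29-fold lower there. Of 19 measured importins and other nuclear transport genes, 7 rose and none fell (10 and none adjusted over the list alone), with a median of 0.39 (adjusted p = 0.00566; adjusted p = 0.668 with an estimated correlation). Kpna2 rose 1.76-fold (second probe 0.19), Nup153 1.77-fold and Kpna6 1.40-fold (second probe -0.17), while Xpo1 rose by 0.39 on the log2 scale. This call ended with the slide as a block (adjusted p = 0.181, median 0.26). Of 19 Rab and Ral partners of the exocyst, 5 rose and none fell, with a median of 0.30 (adjusted p = 0.112). The small GTPase Cdc42 rose 2.21-fold on its brightest probe, and its second probe read 0.17.

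Markers of the cell types of liver moved in both directions. Of 26 measured markers of sinusoidal endothelium, 11 rose and 1, Dnase1l3, fell, with a median of 0.43 (adjusted p = 0.00302; adjusted p = 0.668 with an estimated correlation). Esam rose 2.00-fold (SE 0.10), Stab2 1.98-fold (SE 0.10), Flt1 1.67-fold and Stab1 1.80-fold. After cyclic loess the median of this list was 0.28. Of 24 Kupffer cell and macrophage markers, 8 rose and 1, Cd14, fell, with a median of 0.37 (adjusted p = 0.0364; adjusted p = 0.668 with an estimated correlation). The scavenger receptors Marco and Msr1 rose 3.38-fold (SE 0.25) and 2.44-fold (SE 0.18), and Fcna 2.46-fold. Of 20 monocyte and dendritic cell markers, 4 fell and 1, Fn1, rose, with a median of -0.32 (adjusted p = 0.0333; adjusted p = 0.492 with an estimated correlation). Cd74, the MHC class II invariant chain, fell by 1.74 (SE 0.22), Vcan fell by 1.04, H2-Eb1 fell by 0.55 and Batf3 fell by 0.41 on the log2 scale. These 3 calls ended with the slide as a block (adjusted p = 0.181, 0.402 and 0.154, medians 0.19, 0.22 and -0.17). Markers of T and NK cells (3 of 22 rose and 6 fell, median -0.11), B and plasma cells (1 of 15 fell, median -0.01), stem and progenitor cells (4 of 19 rose and 1 fell, median 0.20), cholangiocytes (1 of 18 rose and 3 fell, median -0.02) and stellate cells (7 of 26 rose and 3 fell, median 0.15) did not pass the list test. Hepatocyte markers rose in 12 of 33 (median 0.27, adjusted p = 0.0118; adjusted p = 0.686 with an estimated correlation), but after cyclic loess their median was -0.01, and with the slide as a block the call ended (adjusted p = 0.33). Cytosolic ribosomal proteins rose in 37 of 77 (median 0.35, adjusted p = 5.49e-09; adjusted p = 0.492 with an estimated correlation), with Rpl3 1.92-fold and Rpl5 1.68-fold higher. Their median after cyclic loess was 0.07 (adjusted p = 0.129), and within slide 1 it was 0.34 (adjusted p = 4.77e-07 with the slide as a block).

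Further lists passed the test at the preset correlation. Of 31 genes of amino acid and urea metabolism, 15 rose and none fell (19 and none adjusted over the list alone), with a median of 0.54 (adjusted p = 3.76e-05; adjusted p = 0.668 with an estimated correlation), led by Sds, Agxt and Asl. Of 37 measured cell cycle genes, 11 rose and 2 fell, with a median of 0.50 (adjusted p = 0.00355; adjusted p = 0.686 with an estimated correlation). Among them Rrm2, Mki67 and Plk1 rose, whereas Ccnb1 fell by 2.15 on the log2 scale (second probe -0.08). Of 32 lysosome and autophagy genes, 14 rose and 1 fell (median 0.42, adjusted p = 0.0028; adjusted p = 0.668 with an estimated correlation). Of 10 measured major urinary proteins, 2 fell and none rose (median -0.22, adjusted p = 0.0159; adjusted p = 0.713 with an estimated correlation). These 4 lists kept their call after cyclic loess and lost it with the slide as a block (adjusted p between 0.0546 and 0.375). After cyclic loess their medians were 0.26 for amino acid and urea metabolism, 0.50 for cell cycle genes, 0.20 for lysosome and autophagy and -0.52 for major urinary proteins. Periportal genes (9 of 32 rose, median 0.27), complement and coagulation (16 of 42 rose and 2 fell, median 0.26), proteasome subunits (10 of 31 rose, median 0.33), p53 targets (5 of 20 rose and 1 fell, median 0.34) and muscle markers (3 of 11 fell, median -0.29) lost their call in both settings.

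**Figure D3:**
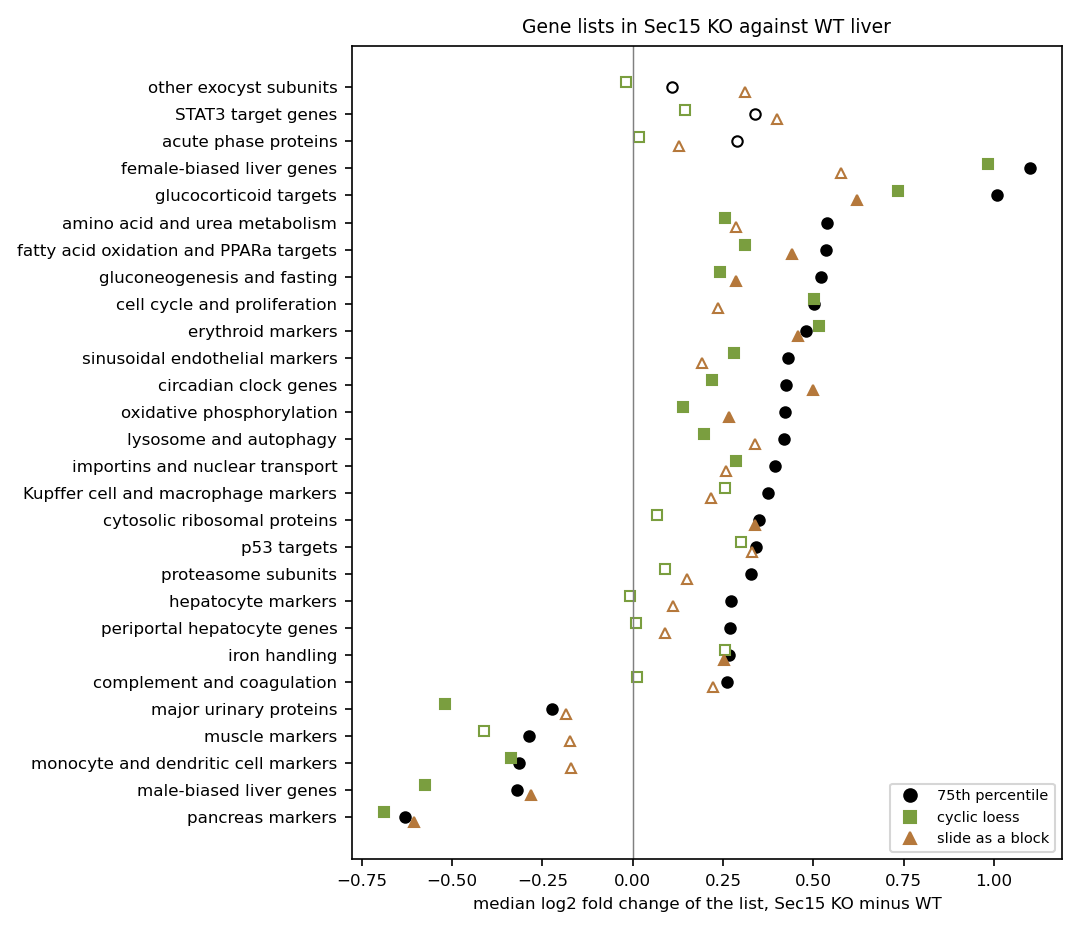
Median log2 fold change (Sec15 KO minus WT) of each list past an adjusted p of 0.05, and of acute phase proteins, STAT3 target genes and other exocyst subunits, with the 75th percentile scaling (circles), after cyclic loess (squares) and with the slide as a block (triangles). Filled symbols have a camera adjusted p under 0.05 at the preset correlation. Hepatocyte markers and cytosolic ribosomal proteins lie near 0 after cyclic loess, at -0.01 and 0.07.

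The similarity of the arrays was described by correlation and by principal components. Over all genes tested, Pearson's r was between 0.980 and 0.991 within WT. KO replicates 1 and 3, both on slide 2, correlated at 0.993, and KO replicate 2 correlated with them at 0.970 and 0.975. KO replicate 2 correlated with WT replicates 1, 2 and 3, on its own slide, at 0.974, 0.958 and 0.967. KO replicates 1 and 3 correlated with the WT arrays at between 0.937 and 0.962. These correlations are across genes, which are not independent replicates. The first principal component, with 67.8% of the variance, placed the 3 WT arrays between -68.6 and -35.5, KO replicate 2 at 14.2 and KO replicates 1 and 3 at 74.7 and 69.5. The second, with 16.0%, set KO replicate 2 (58.9) apart from the other arrays (between -22.7 and 4.50). No pair of arrays had identical values.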

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

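Cyclic loess and slide 1 alone were chosen after the data were seen. The cause of the changes below was not tested. In each parenthesis the first value is the list's median log2 fold change and the next its adjusted p. Of the named genes' values, 480 kept direction and call, 78 kept their direction and lost the call, and none reversed. Of the lists' values, 105 lost a call, 19 gained one and 1 that had a call reversed. The other 1092 either kept direction and call or had no call in either setting. Lists without a call were not compared for direction, and some of them changed sign. Probes well above background numbered 64.8% to 70.3% per array, which limits what dim genes can show.

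With normexp and quantile normalisation 197 genes were at least 2-fold higher and 725 lower. Without a filter 2613 genes were higher at the adjusted threshold. With array weights 12298 were higher and 9946 lower, and 2758 were at least 2-fold lower. These weights ran from 0.0362 to 250 and left the fit to WT replicate 3 (76.9) and KO replicate 3 (250). A block for the slide gave 1158 genes higher and 1067 lower, and 11 lists passed. On slide 1 alone limma called 0 higher and 0 lower, and 6760 at an unadjusted p under 0.05, with 11 lists. After cyclic loess 2472 were higher and 2852 lower, and 16 lists passed. With an estimated correlation 0 lists passed, also where it lay below the preset one, and 32 passed with fry.

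Leaving out each replicate gave between 341 and 5728 genes higher and between 276 and 5069 lower. The counts were 1186 and 1073 without WT replicate 2, 341 and 276 without WT replicate 3, 1484 and 1194 without KO replicate 1, 476 and 519 without KO replicate 3, and 5728 and 5069 without KO replicate 2. The Exoc6b probe ranged from -0.65 to -0.41 and kept its call without WT replicate 1 alone. It also lost its call with median centring (-0.41, adjusted p = 0.11), no filter (-0.53, adjusted p = 0.0699), the slide as a block (-0.58, adjusted p = 0.128) and slide 1 alone (-0.58, adjusted p = 0.191). Its adjusted p ranged from 1.08e-09 to 0.191.

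The values do not settle whether the replicate numbers pair the samples. Deviations from the group mean correlated at 0.11 for both the first and the second numbers, the highest values found. For the third number it was 0.02, and KO replicate 3 correlated best with WT replicate 1 (0.04). With the number as a block 2921 genes were higher and 2394 lower, and the Exoc6b probe lost its call (-0.53, adjusted p = 0.0876).

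With quantile normalisation Kupffer cell markers (0.34, 0.0566), hepatocyte markers (0.22, 0.191), periportal genes (0.22, 0.128), p53 targets (0.40, 0.0707), complement and coagulation (0.083, 0.702), ribosomal proteins (0.058, 0.542), proteasome subunits (0.14, 0.219) and muscle markers (-0.31, 0.27) lost their call, and cholesterol synthesis (-0.33, 0.0426) gained one. With normexp these were iron handling (0.17, 0.0549), monocyte and dendritic cell markers (-0.10, 0.0937), hepatocyte markers (0.14, 0.187), periportal genes (0.17, 0.107), p53 targets (0.18, 0.0595), complement and coagulation (0.086, 0.588), ribosomal proteins (0.056, 0.346), proteasome subunits (0.12, 0.294) and muscle markers (-0.16, 0.0595), and again cholesterol synthesis gained one (-0.23, 0.0391). With median centring Kupffer cell markers (0.49, 0.0688), p53 targets (0.46, 0.0685) and muscle markers (-0.17, 0.0697) lost their call. With a filter on all 6 arrays Kupffer cell markers (0.37, 0.132) and p53 targets (0.34, 0.0626) did.

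With array weights erythroid markers (0.48, 0.0907), monocyte and dendritic cell markers (-0.37, 0.0743) and p53 targets (0.43, 0.0791) lost their call, and pericentral genes (0.38, 0.0446) and MHC class I genes (0.23, 0.0446) gained one. With the mean of the probes Kupffer cell markers (0.26, 0.106), p53 targets (0.32, 0.0934) and muscle markers (-0.29, 0.0815) lost it, and acute phase proteins gained one (0.30, 0.0356). With WT replicates 1 and 2 averaged, monocyte and dendritic cell markers lost it (-0.30, 0.053).

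Calls ended with a block for the slide for importins (0.26, 0.181), female-biased genes (0.58, 0.109), Kupffer cell (0.22, 0.402), monocyte and dendritic cell (-0.17, 0.154), sinusoidal endothelial (0.19, 0.181), hepatocyte (0.11, 0.33) and muscle markers (-0.17, 0.26), periportal genes (0.089, 0.409), amino acid metabolism (0.29, 0.0546), cell cycle (0.24, 0.375), p53 targets (0.33, 0.0894), complement and coagulation (0.22, 0.0902), proteasome subunits (0.15, 0.066), lysosome (0.34, 0.0894) and major urinary proteins (-0.18, 0.0894). Cholesterol synthesis gained a call (-0.39, 0.000352). On slide 1 alone the medians and the lists that changed were the same.

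After cyclic loess hepatocyte markers reversed (-0.0071, 0.913). Calls ended for iron handling (0.25, 0.0835), Kupffer cell markers (0.25, 0.0591), periportal genes (0.0098, 0.344), p53 targets (0.30, 0.072), complement and coagulation (0.011, 0.836), ribosomal proteins (0.067, 0.129), proteasome subunits (0.089, 0.344) and muscle markers (-0.41, 0.344).

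With an estimated correlation, which leaves the medians as they are, calls ended for importins (0.39), male-biased (-0.32) and female-biased genes (1.1), iron handling (0.27), erythroid (0.48), Kupffer cell (0.37), monocyte and dendritic cell (-0.32), sinusoidal endothelial (0.43), hepatocyte (0.27), pancreas (-0.63) and muscle markers (-0.29), periportal genes (0.27), PPARa targets (0.54), gluconeogenesis (0.52), amino acid metabolism (0.54), clock genes (0.42), cell cycle (0.50), p53 (0.34) and glucocorticoid targets (1.01), complement and coagulation (0.26), oxidative phosphorylation (0.42), ribosomal proteins (0.35), proteasome subunits (0.33), lysosome (0.42) and major urinary proteins (-0.22). Fry, which does not compare a list with other genes, called exocyst partners (0.30, 0.00908), STAT3 targets (0.34, 0.0316), acute phase proteins (0.29, 0.0388), the growth hormone axis (0.35, 0.0175), stem and progenitor markers (0.20, 0.0484), secreted factors (0.15, 0.0198), adipose markers (0.11, 0.0387) and fetal liver genes (-0.029, 0.0143), and not major urinary proteins (-0.22, 0.145).

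Without single replicates, medians ranged from 0.19 to 0.36 for acute phase proteins, which passed without KO replicate 2 (0.31, 0.0498). They ranged from 0.27 to 0.47 for Kupffer cell markers (call lost without WT replicate 2 or KO replicate 1), from -0.41 to -0.19 for monocyte and dendritic cell markers (KO replicate 1), from 0.26 to 0.45 for p53 targets (WT replicate 2, KO replicate 1 or 2), from -0.34 to -0.14 for major urinary proteins (WT replicate 2 or KO replicate 2) and from -0.43 to -0.19 for muscle markers (WT replicate 2 or 3, KO replicate 1 or 3). Calls were gained by pericentral genes (0.19 to 0.40) and xenobiotic metabolism (0.094 to 0.46) without KO replicate 2, and by cholesterol synthesis (-0.43 to -0.14) without KO replicate 1.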

Other observations

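The tests of nonspecific signal, of blood left in the tissue and of female animals were chosen before their results were seen, and the other tests after. For cholesterol synthesis the median log2 fold change was -0.40, with 1 of 27 genes higher and 3 lower, and did not pass the list test (adjusted p = 0.211). The median was -0.39 with the slide as a block (adjusted p = 0.000352), where the difference rests on KO replicate 2 alone among the KO arrays. Its adjusted p ranged from 0.000137 to 0.818 over the alternatives, the highest with an estimated correlation.

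Neutrophil markers moved both ways, with 5 of 22 higher and 3 lower, a median of -0.17 and a mean of 0.17. Retnlg and S100a8 rose by 2.19 and 2.72 on the log2 scale and Itgam fell by 1.38. Fetal liver genes also had a median (-0.03) and mean (0.17) of opposite sign, with 5 of 17 higher and 1 lower.

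Large falls outnumbered large rises. Whether the slide is their cause cannot be told apart from genotype, since 1 KO array shares the slide of the WT arrays. Genes at least 2-fold lower were picked without KO replicate 2 and 1 WT array. The median of KO replicate 2 minus that WT array, which had no part in the pick, was between -0.82 and -0.50. The spread at the value nearest 0 was 0.02 over 2698 resampled genes and does not measure differences between arrays. A slide effect alone would give 0 only if the arrays of slide 1 did not differ otherwise. Over 2480 genes picked without KO replicate 2 alone, the median against WT was -1.57 in KO replicates 1 and 3 and -0.70 in KO replicate 2. For 784 rises these were 1.25 and 0.93. The pick itself enlarges the first value of each pair. Signal not specific to the probe's gene may account for part of the falls. Of the 1685 genes, 177 had a second probe, which showed a median share of 0.128 (spread 0.038) of the fall. For rises the share was 0.236 (spread 0.070). The genes were picked by the change on their brightest probe, which by itself lowers the share on a second, dimmer probe. The test therefore cannot tell nonspecific signal from this effect of the pick. Sensory receptor genes fell by 2-fold 2.42 times as often as other genes of the same brightness (spread 0.19), which fits loss of signal from genes that liver does not use. That comparison covers genes past the filter, and the median of these receptors was -0.125 without a filter and -0.44 with a filter on all 6 arrays. In KO replicate 2 against the WT mean their median was -0.108, while over all KO arrays it was -0.533. Their fall thus rests mostly on the KO arrays of slide 2, where slide and genotype cannot be told apart. A biological effect of Sec15 loss on part of the genes that fell stays open, as does an effect of the slide.

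Of 31 erythroid markers, 14 rose and 5 fell. A like rise of all blood cells needed a median of 0.24 in T, NK, B and plasma cell markers. Theirs was -0.068 (spread 0.25), and the gap is little more than the spread. These markers were not matched for brightness, which the changes followed. After cyclic loess, which removes differences that follow brightness, the medians of the T and NK and the B and plasma lists were negative. That of the erythroid list stayed positive. These values argue only weakly against a like rise, and they cover lymphocytes alone. The neutrophil genes S100a8, S100a9 and Retnlg rose by 2.72, 2.33 and 2.19 on the log2 scale, and the platelet genes Pf4 and Clec1b rose by 0.90 and 1.16, all chosen after their values were seen. The platelet list had 4 of 16 higher and 3 lower, with a median of -0.16. In KO replicate 2 against the WT arrays of its slide the medians were 0.38 for the platelet list and 0.21 for the neutrophil list, the opposite direction. Blood with more red cells, neutrophils or platelets in the tissue therefore stays open. Nor can the slide be told apart from genotype, since 1 KO array shares the WT slide. The median of the list in KO replicate 2 was 0.46 with a spread of 0.47. Of 17 members higher without KO replicate 2 and 1 WT array, 17 (100%) lay above that WT array in KO replicate 2. The share without a change is 50%. Of all 784 genes at least 2-fold higher without KO replicate 2, 95.7% lay above the WT mean in it. That share used the WT arrays of the pick and asked for a 2-fold change, which the pick of the members did not. A high share was thus not particular to this list, though the shares differ in threshold and reference. More red cells or precursors in the liver may explain the rise, and that was not tested.

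Of 24 male-biased genes 10 fell, and of 19 female-biased genes 11 rose. Female animals among the KO samples are argued against by Y-linked Ddx3y and Eif2s3y, well above background on all 6 arrays. Both were higher in KO, by 0.69 and 0.43 on the log2 scale (limma adjusted p = 0.0283 and 0.0428). Kdm5d and Uty were well above background on 1 array and on none. Xist (-0.32, SE 0.34) was well above background on 3 WT arrays and 1 KO array, so its difference adds little. The slide cannot be told apart from genotype, since 1 KO array shares the WT slide. The median in KO replicate 2 was -0.28 (spread 0.21) for the male-biased list and 0.58 for the female-biased. Of 28 members changed without KO replicate 2 and 1 WT array, 24 (85.7%) lay beyond that WT array in KO replicate 2. This was the lowest share over the 3 WT arrays, and 50% is the share without a change. Of all genes at least 2-fold changed without KO replicate 2, 95.7% of 784 higher and 80.9% of 2480 lower kept their sign in it. Those shares used the mean of the WT arrays of the pick and asked for a 2-fold change, which the pick of the members did not. A high share was thus not particular to these lists, though the shares differ in threshold and reference. Nor can a less mature liver be told apart, as fetal liver genes had a median of -0.029 (spread 0.21) with members both ways. Altered growth hormone signalling may be another explanation and stays open. The list of its axis had 5 of 12 members higher and none lower, with a median of 0.35 (adjusted p = 0.152 with camera and 0.0175 with fry) and 0.09 after cyclic loess, and RNA levels do not measure the hormone's secretion.

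The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 6747 genes and the highest other 2, and 1 split reached the real count. At least 2-fold changes numbered 2282 against 438 (1 split). For lists it was 25 against 31, with 3 splits as large. The split with 31 lists put WT replicate 1 with KO replicates 1 and 3, and that with 26 put KO replicate 2 with WT replicates 1 and 2. Both set 3 arrays of slide 1, KO replicate 2 among them, against a group that holds both arrays of slide 2, so they follow the slide in part. With the slide as a block 11 lists passed.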
